A study of Bombyx mori with 4 samples.

How the data were processed

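The series holds 4 one-colour arrays of total RNA from silkworm hemocytes, 2 from control and 2 from infested larvae. Per the labels' protocols, 500 ng of RNA was amplified from an oligo-dT primer and labelled with Cy3. Per the file headers, the arrays were read with Agilent Feature Extraction 11.5.1.1, and all 4 lie on 1 slide and come from 1 scan, so a slide block could not be fitted. Controls and infested samples occupy different positions of that slide, so position and group cannot be told apart.

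Each of the deposited scanner files gives spot intensity values on a linear scale, which the authors' scanner software had background-subtracted and detrended, per the file headers, to make the processed signal. The deposited series table holds log2 values. Each of its columns correlated above 0.999 with the log2 processed signal of its own array and all have a median of 4.13, as after quantile normalization; the software used for this is not given in the sources used here. Of its 34230 probes, 34223 are among the probes used here. The table lacks 7 of those used here and holds 7 left out here for spot flags.

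The main values were log2 of the processed signal minus the array's 75th percentile, averaged over the spots of a probe. Control spots and spots flagged as non-uniform or population outliers were left out, which removed 7 of 34237 probes. Saturated spots were kept. Probes well above background on both arrays of at least 1 group were tested, 12007 of them named specific and 8269 named cross-hybridising by the array design. For each gene identifier the probe with the highest mean was used. Differences were tested with limma 3.58.1 (lmFit and eBayes, group only, two-sided) in R 4.3.3, with the package data.table (version 1.17.8) and Benjamini-Hochberg adjustment over all tested probes. With 2 arrays per group, 2 residual degrees of freedom remain and the number of arrays limits the precision.

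Where a probe was not well above background on any array of a group, the fold is a bound, taken against the mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. Gene names are those of the array design, which repeats some descriptions over many unrelated ESTs. Of 118 RefSeq accessions on the array, 41 matched the reference gene table; the design's name was kept for the rest. No coordinates were used.

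Before the data were examined, 26 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The lists are antimicrobial peptides and lysozymes, pattern recognition, Toll, IMD and JAK-STAT signalling, melanisation, serine protease inhibitors, apoptosis, autophagy, oxidative stress defence, heat shock proteins and chaperones, xenobiotic metabolism, cytoskeleton, cell adhesion and extracellular matrix, calcium signalling, lysosome and V-ATPase, cytoplasmic ribosomal proteins, proteasome, mitochondrial respiratory chain, glycolysis, DNA replication and cell cycle, juvenile hormone and ecdysone, and markers of hemocytes, fat body, epidermis and cuticle, silk gland, midgut and muscle. Members were matched by words in the description, so a few do not belong, such as fibrohexamerin in the fat body list. Lists were tested with camera at a preset correlation of 0.01, two-sided, and again with an estimated correlation and with fry; none of the 26 passed under either of these, where the smallest adjusted p was 0.86 and 0.204. Named genes were the 12 per direction with a described product, both infested arrays on one side of both controls and the largest difference among those past the threshold, filled by the smallest unadjusted p where fewer passed, plus up to 4 members per list with the smallest p. Other identifiers in the text, including the cecropin-D, 30K lipoprotein, arylphorin, transferrin and proteinase values, were chosen after their values were seen.

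The limma step was tested on simulated arrays of 20276 probes with 50 probes changed at each of 4 sizes. It recovered 30% of changes of 2 on the log2 scale, 86% of 4, 100% of 6 and 100% of 8, with 9 false calls. The list step, over 16385 simulated genes, passed 0 of 26 lists with no change and recovered a list of 40 genes shifted by 1. These genes were drawn independently of each other. In the data the estimated correlation was 0.425 for the antimicrobial, 0.222 for the melanisation, 0.166 for the heat shock and 0.0762 for the fat body list. The simulation therefore cannot say how often a list of correlated genes passes without a change.

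Alternatives covered background correction (normexp, offset 50), quantile normalization, centring on the median, the percentile over probes detected on all arrays, no filter, a filter on all 4 arrays, the authors' values, eBayes with trend and robust, a replicate block, each array left out in turn, looser and stricter thresholds and the mean of a gene's probes. Added after seeing the data were a floor at the lowest detected level, specific probes only and pruned lists. Pruned lists left out unclear members and kept a single identifier per product name.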

Results

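Transcript levels were measured in hemocytes, the circulating blood cells that carry much of the insect cellular immune response, of the silkworm Bombyx mori. The study compared control larvae with larvae invaded by maggots of the uzi fly Exorista bombycis, a parasitic fly whose maggots bore through the larval skin. Infestation took place on day 1 of the fifth instar, and cells were pelleted from hemolymph 6 h after invasion. There were 2 control and 2 infested samples, each on 1 one-colour array. The labels do not say whether the samples of a group came from separate larvae or pools, so p-values measure only the spread between these samples, which may be technical. Of 34230 probes with a value on all 4 arrays, between 57.8% and 62.4% per array were well above background, and 20276 entered the test, covering 16385 gene or EST identifiers. Across probes, which are not independent replicates, Pearson's r was 0.982 between the control arrays, 0.978 between the infested arrays and 0.962 to 0.973 between arrays of different groups. The SD of log2 differences was 0.639 and 0.727 within groups and 0.778 to 0.957 between them.

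The comparison of infested with control hemocytes addresses which transcripts differed 6 h after the maggot entered. Sprouty (Gene007625), a feedback inhibitor of receptor tyrosine kinase signalling, fell by 3.79 on the log2 scale (SE 0.266, limma adjusted p = 0.0423, n = 2 per group), from a mean of 3.87 ± 0.0379 (SD) in control to 0.0848 ± 0.22 in infested arrays, relative to each array's 75th percentile. A pair of identifiers described as Bm8 interacting protein m-9 also fell, Gene014195 by 3.99 (SE 0.274) and Gene014194 by 3.54 (SE 0.281), both with a limma adjusted p of 0.0423. The Gene014195 probe was cross-hybridising and the Gene014194 probe specific, so the pair may share signal. Cyclophilin-9 (Gene004508), a member of a family of peptidyl-prolyl isomerases, rose by 3.30 (SE 0.274, limma adjusted p = 0.0443), a 9.86-fold difference. These 4 identifiers were well above background on all 4 arrays and lay on the same side in both infested arrays.

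The remaining named genes past the threshold were not well above background on either array of one group, so their differences are bounds. Abhydrolase domain containing 11 (Gene009706) was at least 53.4-fold higher in infested hemocytes (limma adjusted p = 0.00721), and an EST described as RNA-dependent RNA polymerase (E_FL_fcaL_50E23_R_0), measured with a cross-hybridising probe, at least 10.7-fold higher (limma adjusted p = 0.0423). In the other direction, a putative cuticle protein (Gene016650) was at least 18-fold lower, the transport protein USO1 (Gene005514) at least 9.54-fold, LigA (Gene008114) at least 5.07-fold and a putative membrane protein (Gene009165) at least 4.47-fold lower, each with a limma adjusted p of 0.0423. Probes that went from background to at least 32-fold brighter numbered 51 between the control arrays, all bright in control replicate 1, 33 between the infested arrays and 30 to 64 between arrays of different groups. The probes of Gene009706, E_FL_fcaL_50E23_R_0 and Gene016650 are among those that switched between groups. Another EST described as putative RNA dependent RNA polymerase (eGene21942, cross-hybridising) did not enter the test. It differed by -2.21 and was brightest on control replicate 1.

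**Figure D1:**
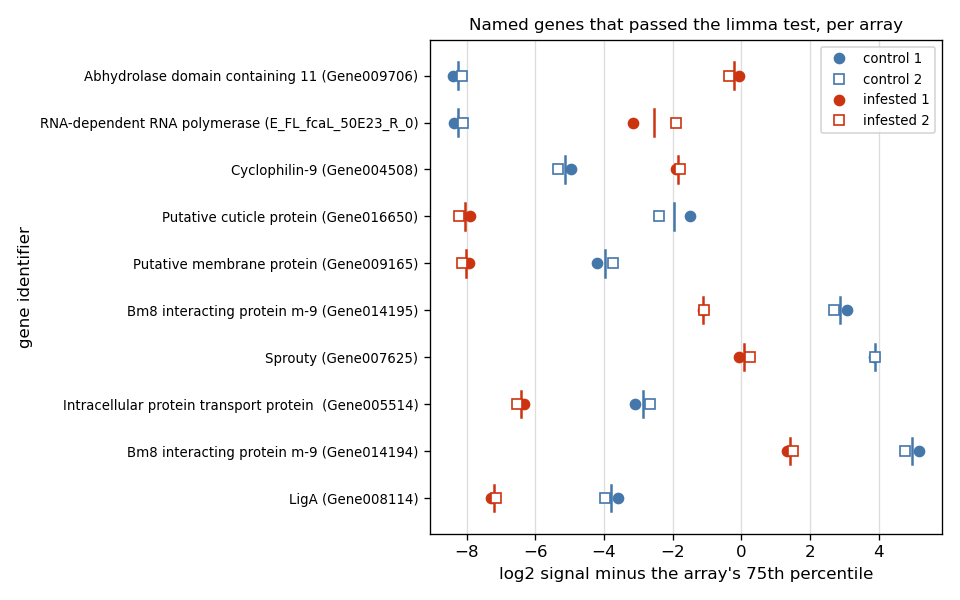
Normalised log2 signal (horizontal axis, log2 units relative to the array's 75th percentile) of the 10 named genes that passed the test (vertical axis), with 1 point per array and a vertical bar at each group's mean. For Sprouty (Gene007625) the control arrays sit at 3.85 and 3.9 and the infested arrays at -0.0706 and 0.24.

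In all, limma called 6 probes higher and 14 lower in infested hemocytes at an adjusted p under 0.05, and 14 of these 20 probes were not well above background on either array of one group. Among the 6, eGene18671 and E_FL_fcaL_50E23_R_0 had nearly equal values on each array. So did Gene002360 and Gene002361 in infested hemocytes. All of these probes were cross-hybridising, so each pair may share signal. An unadjusted p under 0.05 was reached by 1073 probes with a higher and 1727 with a lower mean in infested hemocytes. The infested arrays lay wholly above or wholly below the control arrays for 47.8% of probes, where chance gives 33.3%. Leaving out 1 array ended most calls: without control replicate 2, infested replicate 1 or infested replicate 2 limma made 0 calls (1568, 4136 and 2756 probes at an unadjusted p under 0.05), and without control replicate 1 it made 8 and 12, among which 4 of the 20 remained. Quantile normalization left 3 higher and 0 lower, normexp background correction left 0 and 0 (2597 at an unadjusted p under 0.05), and centring on the median gave 9 and 18.

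The other named genes did not pass and were those with the smallest p-values among described products. Fatty-acyl CoA reductase II, which makes fatty alcohols, had log2 differences of 4.67 (Gene007089, SE 0.55) and 4.52 (Gene007090, SE 0.495), and carboxylesterase CarE-12 (Gene015890) one of 4.08 (SE 0.433), each with a limma adjusted p of 0.0612. Protein singed wings 2 (Gene004440) had a difference of 2.72 (limma adjusted p = 0.0631), a retroelement polyprotein (Gene004297) 2.04 and the transposase yabusame-1 (Gene012787) 2.91 (limma adjusted p = 0.0631 and 0.0639). NADPH oxidoreductase (Gene003361), chorion class A protein L12 (eGene17229) and the dynein light chain Tctex-type 1 (Gene003892) were not well above background in control hemocytes, with bounds of at least 3.93-fold, 3.49-fold and 2.15-fold higher. The NADPH oxidoreductase, chorion and retroelement probes were cross-hybridising. On the lower side, the vesicle tethering factor p115 (Gene001170) and peritrophin type-A domain protein 2 (E_FL_bmmt_07N24_R_0) were not well above background in infested hemocytes, with bounds of at least 5.83-fold and 2.38-fold lower and a limma adjusted p of 0.058 for both. That peritrophin probe was cross-hybridising. Another identifier with the same description (ceN-1454), measured with a specific probe, went the other way, at 1.78 (limma adjusted p = 0.0674).

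The fat body list fell as a group. Fat body is the insect's organ of storage and hemolymph protein synthesis, and over 34 identifiers the median log2 difference was -0.71 (limma camera, adjusted p = 3.64e-05; adjusted p = 0.86 with an estimated correlation). No member passed over all probes, and 11 were lower with the p adjusted over the list alone. It held 14 identifiers of the 30K lipoproteins, small hemolymph storage proteins. Of all 24 such identifiers on the array that were tested, 21 were lower in both infested arrays than in both controls, and the median was -4.59 with bounds used for the 6 not well above background in infested hemocytes and the 1 not so in control. Gene011501 averaged 4.38 ± 1.83 (SD, n = 2) in control and -2.31 ± 0.353 in infested arrays, and Gene011502 2.72 ± 1.32 and -3.50 ± 0.923. Both were measured with cross-hybridising probes. The control arrays differed among themselves, at 3.09 and 5.68 for Gene011501. Arylphorin (Gene001347), a storage hexamer, had a difference of -5.35 (SE 0.803, limma adjusted p = 0.0753), and apolipophorin-III (Gene009269), a lipid carrier, one of -1.81, lower with the p adjusted over the list alone (0.0263). Transferrin (Gene013327) differed by -0.15 and the 30kDa proteins Gene011484 and Gene011485 by 0.30 and 0.35, and the 30K lipoprotein Gene011482 was at least 1.29-fold higher without passing. With only probes designed as specific, the list's median was -0.385 (limma camera, adjusted p = 0.0609). With unclear members and repeats of a product name left out, 13 identifiers remained, with a median of -0.596 (limma camera, adjusted p = 0.0964). The median was -0.36 with normexp and -0.468 without control replicate 2, and the list passed in both.

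**Figure D2:**
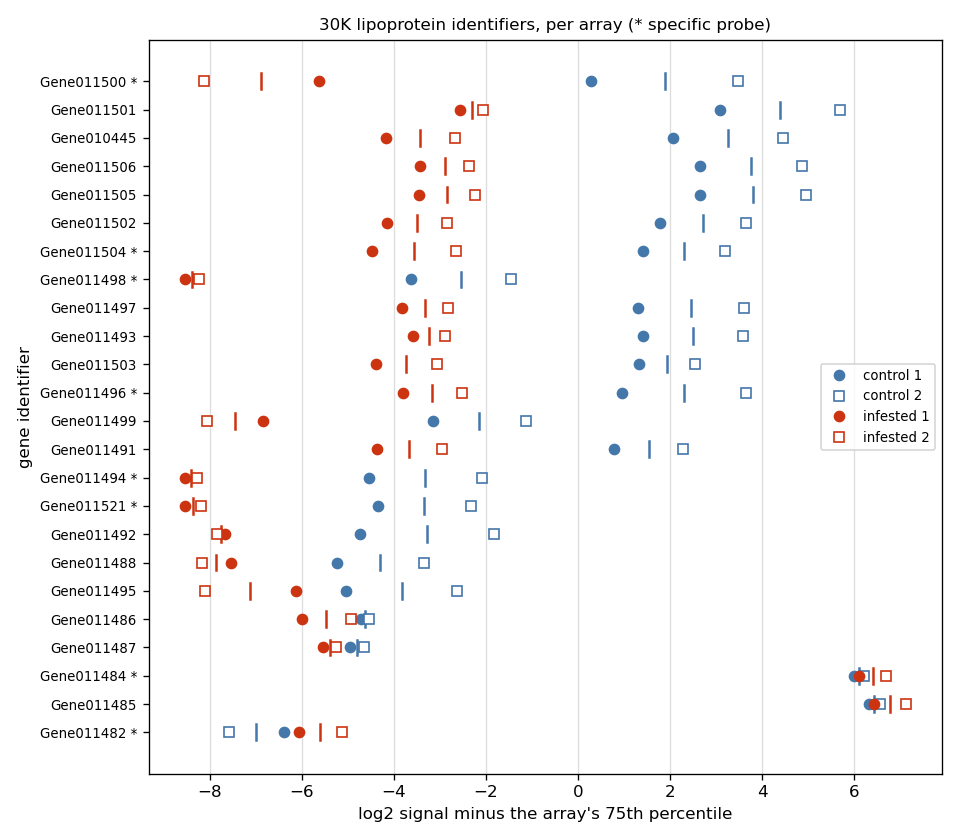
Normalised log2 signal (horizontal axis, log2 units relative to the array's 75th percentile) of 24 identifiers described as 30K lipoproteins (vertical axis, ordered by difference, an asterisk marking probes designed as specific), with 1 point per array and a vertical bar at each group's mean. In 21 of the 24, both infested arrays lie below both control arrays.

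Antimicrobial peptides and lysozymes, the secreted effectors of the insect humoral response, rose as a list, with a median log2 difference of 0.91 over 39 identifiers (limma camera, adjusted p = 0.00105; adjusted p = 0.86 with an estimated correlation). No member passed over all probes or adjusted over the list alone. Enbocin3 (Gene015101) averaged 0.0481 ± 2.26 (SD, n = 2) in control and 3.23 ± 0.481 in infested arrays. Its probe was cross-hybridising, and the control replicates stood at 1.65 and -1.55. Cecropin A (Gene016648) averaged 0.552 ± 0.177 and 2.43 ± 1.28, and a lysozyme (Gene007002) 0.307 ± 1.82 and 3.09 ± 0.793, while the lysozyme EST eGene23369 had a difference of -2.25. Without infested replicate 2 the list median was 0.0219 (limma camera, adjusted p = 0.886), without infested replicate 1 it was 2.17, and without control replicate 2 it was 0.524; with specific probes only the adjusted p was 0.275. Probes for cecropin-D disagreed, at 3.27 (E_FL_MFB-_24N14_F_0, cross-hybridising) and -0.49 (Gene015102, specific).

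Genes of melanisation, the deposition of melanin on wounds and parasites, also rose as a list, with a median of 0.54 over 55 identifiers (limma camera, adjusted p = 0.00627; adjusted p = 0.86 with an estimated correlation). None passed singly, over all probes or adjusted over the list alone. Of 25 serine proteinases and related proteins in it, 12 were higher in both infested arrays, among them hemolymph proteinase 19 (Gene009412) at 1.72 (SE 0.626) and prophenoloxidase-activating proteinase-3 (Gene015619) at 1.13, both without passing. The member with the smallest p, a hemolymph protein (Gene011520, cross-hybridising), went the other way, at -3.58 (SE 0.548, limma adjusted p = 0.0781). Next by p were hemolymph proteinase 18 (Gene016569, at least 1.91-fold higher), Yellow8 (eGene20794) at -1.02 and Yellow-b (Gene004246) at 1.01. Over the whole list 22 identifiers were higher and 7 lower in both infested arrays. Without infested replicate 2 the median was 0.0794 (limma camera, adjusted p = 0.484), with no filter 0.182 (adjusted p = 0.124), and with specific probes only the adjusted p was 0.0525. It passed with medians of 1.03 without infested replicate 1, 0.326 without control replicate 1 and 0.23 with normexp. The melanisation list's median for infested 1 minus infested 2 was -0.84. Pattern recognition genes, with a median of 0.46, did not pass (limma camera, adjusted p = 0.0719), and a peptidoglycan recognition protein (Gene000234) had a difference of 1.06 (SE 0.261). The pattern recognition list passed without control replicate 1 (median 0.7, adjusted p = 0.00193), and its median was 0.0845 without control replicate 2, 0.209 without infested replicate 2 and 0.0681 with normexp.

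Heat shock proteins and chaperones fell as a list of 100 identifiers, with a median of -0.19 (limma camera, adjusted p = 0.046; adjusted p = 0.86 with an estimated correlation). No member passed over all probes, and 6 were lower with the p adjusted over the list alone. Of 42 small heat shock identifiers 20 were lower in both infested arrays, and hsp20.4 (Gene015288) averaged 6.69 ± 0.339 (SD, n = 2) in control and 2.88 ± 0.535 in infested arrays (limma adjusted p = 0.061). The hsp20.4 probe was cross-hybridising. A DnaJ domain protein (Gene016454), a co-chaperone, averaged 5.94 ± 0.198 and 2.73 ± 0.473. Of 21 large heat shock proteins and chaperonins, none reached an unadjusted p under 0.05. Without infested replicate 1 the list had a median of -0.107 and an adjusted p of 0.605 by limma camera, and without control replicate 2 an adjusted p of 0.0953. The median was -0.279 without infested replicate 2, and that for infested 1 minus infested 2 was -0.39, so the fall was larger on infested replicate 1. With centring on the median the list passed at a median of -0.0684. Its limma camera adjusted p was 0.0647 with normexp, 0.0578 with the mean of a gene's probes and 0.124 with no filter. With specific probes only the adjusted p was 0.345, at a median of -0.0821. With unclear members and repeats of a product name left out it was 0.335, at a median of -0.0826.

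Other lists did not pass. Markers of epidermis and cuticle had a median of -0.07 over 117 identifiers (limma camera, adjusted p = 0.107), with 1 member lower over all probes and 17 lower and 2 higher adjusted over the list alone. Larval cuticle protein LCP-17 (Gene004335) averaged -1.82 ± 0.19 (SD, n = 2) in control and -6.01 ± 0.69 in infested arrays, where 1 of 2 arrays was well above background, and Gene013738, another cuticle protein, had a difference of 3.37 and was well above background on 1 of 2 control arrays. The list passed in the lower direction without control replicate 1 (median -0.242, limma camera adjusted p = 0.00193) and with centring on the median (adjusted p = 0.0482), and without control replicate 2 its median was 0.125. Among juvenile hormone and ecdysone genes (median -0.03, adjusted p = 0.484), juvenile hormone epoxide hydrolase-like protein 5 (Gene015452) had a difference of -3.96 (SE 0.38, limma adjusted p = 0.061; well above background on 1 of 2 infested arrays), juvenile hormone acid methyltransferase (Gene015552) one of -1.56, and 4 members were lower and 1 higher adjusted over the list alone. In the xenobiotic list (median 0.07, adjusted p = 0.484), 3 members, among them CYP4G25 (Gene001399, at least 2.57-fold lower, not well above background in infested hemocytes), were lower and 1 higher on that basis. Hemocyte markers had a median of -0.16 and a mean of 0.0852 (limma camera, adjusted p = 0.475), with hemocytin (Gene005354), a clotting protein, at -1.98 (SE 0.341) and hemocyte-specific integrin alpha subunit 1 (Gene005409) at 1.04 (SE 0.283). The hemocytin probe was cross-hybridising. The hemocyte median was above 0 with specific probes only (0.432, limma camera adjusted p = 0.0609), with quantile normalization (0.00703) and without infested replicate 1 (0.112). It was 0.253 with unclear members and repeats of a product name left out.

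Median log2 differences of the remaining lists were -0.18 for cytoplasmic ribosomal proteins and 0.32 for serine protease inhibitors (limma camera, adjusted p = 0.0719 for both). Ribosomal proteins passed by limma camera with normexp (-0.156, adjusted p = 0.0446) and over probes well above background on all 4 arrays (adjusted p = 0.0389). With 1 array left out, a group holds 1 array, so only medians are given, which does not mean that they failed to pass. These were -0.292 without control replicate 1, -0.198 without infested replicate 2 and -0.0621 without control replicate 2. Their median was -0.028 with quantile normalization and -0.0273 with the authors' values, and they did not pass in either. Serine protease inhibitors had medians of 0.382 without control replicate 1 and 0.473 without infested replicate 1, likewise given without the test. They passed by limma camera over probes well above background on all 4 arrays (adjusted p = 0.0375). With unclear members and repeats of a product name left out, they passed by limma camera at 0.406 (adjusted p = 0.0435). They stood at 0.212 without control replicate 2, 0.139 without infested replicate 2 and 0.13 with normexp. With no filter the sign turned, to -0.0141 over 83 identifiers. The lysosome and V-ATPase list stood at 0.14, autophagy at 0.29 and muscle markers at -0.38, with limma camera adjusted p of 0.15, 0.159 and 0.244. Autophagy stood at 0.165 without infested replicate 2 and muscle markers at -0.158 without control replicate 1. The lysosome list passed without infested replicate 1 (0.175, adjusted p = 0.0447) and with normexp (0.0982, adjusted p = 0.0371), and stood at 0.0609 without infested replicate 2. Apoptosis stood at 0.10, oxidative stress defence at 0.04, proteasome at -0.18 and DNA replication and cell cycle at -0.14, each with an adjusted p of 0.378. Oxidative stress defence passed without infested replicate 1 (0.237, adjusted p = 0.0447) and stood at -0.145 without infested replicate 2, and the proteasome passed without infested replicate 2 (-0.32, adjusted p = 0.046) and stood at -0.0567 without infested replicate 1. Glycolysis stood at -0.16, the cytoskeleton at 0.04, cell adhesion and extracellular matrix at 0.03, and Toll, IMD and JAK-STAT signalling at -0.19, with limma camera adjusted p of 0.58, 0.583, 0.642 and 0.642. The Toll, IMD and JAK-STAT median was -0.0635 without control replicate 2 and -0.0889 without infested replicate 2. Mitochondrial respiratory chain genes and silk gland markers stood at -0.06 and -0.07 (adjusted p = 0.78 for both), calcium signalling at 0.01 (0.838) and midgut markers at -0.03 (0.978). The camera direction was up for the hemocyte, silk gland, midgut and respiratory chain lists although their medians were below 0. Leaving out 1 array turned the sign of the median of the cytoskeleton, cell adhesion, calcium signalling, glycolysis, respiratory chain, silk gland and midgut lists, none of which passed in those runs.

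**Figure D3:**
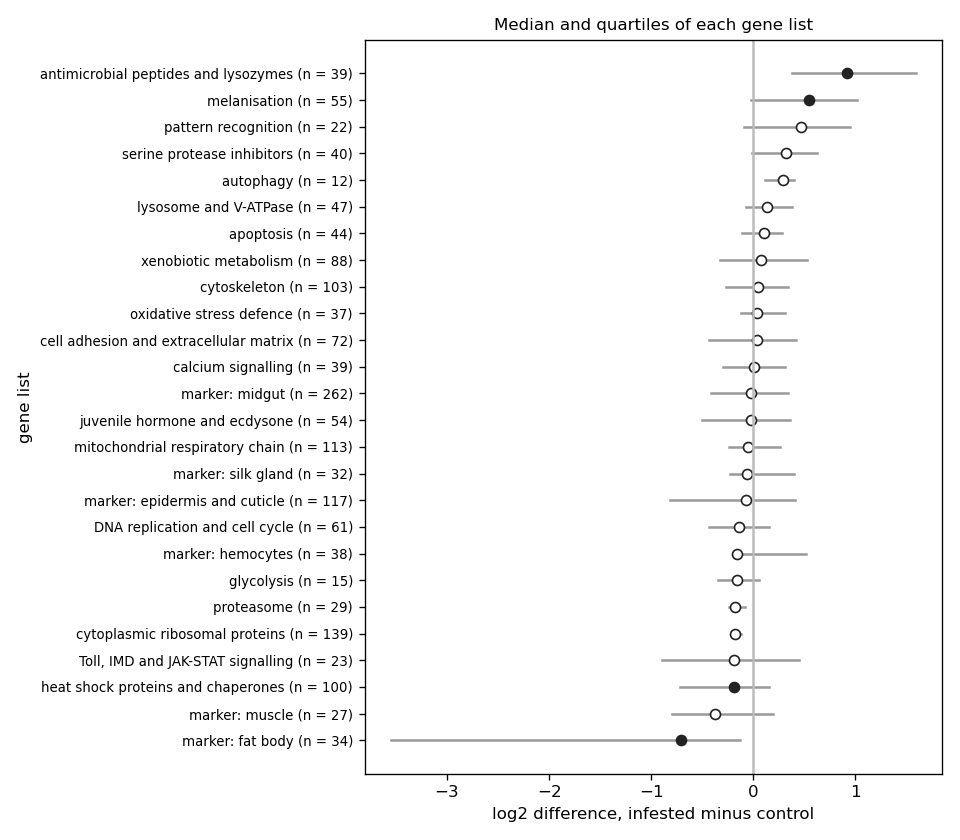
Median log2 difference, infested minus control (horizontal axis, log2 units), of the members of each of 26 gene lists (vertical axis, n the number of identifiers), with lines from the lower to the upper quartile of members. Filled points mark the 4 lists with a camera adjusted p under 0.05, with medians of -0.71, -0.19, 0.54 and 0.91.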

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

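The tests of shared signal between paralogs and those on the antimicrobial peptides were chosen after the results they concern had been seen. Probes for the genome of the nucleopolyhedrovirus BmNPV, a silkworm pathogen, were nearly all too dark to enter the comparison of the groups, which tested 2 of 169 and called neither, yet 33 were well above background in infested replicate 1. The control arrays had 6 and 4 and infested replicate 2 had 1. The 33 probes belong to 19 viral identifiers, and 31 of them were well above background on that array alone. The 3 probes of the viral DBP gene averaged -3.65 ± 0.15 (SD over probes) there, against -7.75, -8.08 and -7.27 on control 1, control 2 and infested 2. The 3 probes of viral FGF averaged -4.43 ± 0.14 there, against -7.94, -8.09 and -8.21. Probes named for other species were well above background at 12.7% on that array and at 10% to 13.4% on the others.

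The fall of 30K lipoproteins could reflect signal shared between paralogs, but the 8 probes designed as specific had a median of -3.2 with bounds where a group was not well above background, 6 of them under -2, which argues against it as the whole cause. Fat body tissue carried over into the control pellets remains open: transferrin, apolipophorin and vitellogenin identifiers had a median of -0.575, between the bounds of -1 and -0.5 set in advance, and these are also bright in hemocytes of both groups. Control replicate 2 lay above control replicate 1 in 23 of the 24, with medians of 2.87 and 0.869. A difference between infested and control hemocytes stays among the open explanations, untested.

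In all, 116 probes were not well above background on one array and at least 32-fold brighter on another. Of the 24 printed in duplicate, 0% had spots differing by over 2-fold on the bright array, which argues against a damaged or misread spot there. Spots on the dark array were not compared, and probes without duplicates could not be checked. Sequence variants of the larvae against the probes may account for some of the 116. The mean number of such probes per between-group pair of arrays was 1.08 times that per within-group pair (1.22 by identifiers). Of 11 identifiers with another bright probe, that probe moved by under 1 on the log2 scale in 6 and by over 3 in 0. With 1 array left out the ratio ran from 0.853 to 1.55 by probes and from 0.925 to 1.83 by identifiers, and both highest values, without control replicate 1, lie between the bounds set in advance (under 1.5 for this explanation, over 3 against it), so the reading rests on that array. All 51 between the control arrays were bright in control replicate 1, and by pattern 24 probes of 22 identifiers were dark on control replicate 2 alone, 30 probes of 21 identifiers were bright on both arrays numbered 1 alone, 10 of them probes of a V-ATPase subunit M9.7 identifier (eGene22183), 14 probes of 14 identifiers on both control arrays alone and 11 of 9 on both infested arrays alone. Among the called probes, those of Gene009706, Gene002360, Gene002361, eGene18671 and E_FL_fcaL_50E23_R_0 were bright on both infested arrays alone. Those of Gene016650 and E_FL_bmmt_28H15_F_0 were bright on both control arrays alone. Sequence variants were not tested for these called probes singly. The 14 probes bright on both control arrays alone also include 30K lipoproteins, such as Gene011494 and Gene011498, and cuticle proteins, such as Gene012657. Both families are described above. The ratio of between-group to within-group counts cannot tell sequence variants from differences between samples in expression or carried-over tissue. No biological explanation was tested.

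Antimicrobial peptides and lysozymes differed between the control arrays, with a median of 0.747 for control 1 minus control 2. The infested arrays differed by more, with a median of -1.52 for infested 1 minus infested 2. That gap is larger than the list's median difference between the groups, 0.912. Scaling of the arrays is argued against, since 10000 random lists matched on mean control level had medians of -0.262 to 0.342, centred on 0.0187. Quantile normalization moved the ribosomal list from -0.217 to -0.0212 and left the antimicrobial list at 0.754. Immune activation of the larvae of control replicate 1 may be involved and stays open, since pattern recognition genes differed by 0.223, between the bounds of 0.1 and 0.5. On the same measure the melanisation list differed by -0.18 and the Toll, IMD and JAK-STAT list by 0.02. For infested 1 minus infested 2 the pattern recognition median was -0.0035, against -1.52 for the antimicrobial list. Pattern recognition genes did not follow the antimicrobial list there, so they cannot decide on immune activation.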

How the results depend on the processing

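The floor, the specific probes and the pruned lists were chosen after seeing the data. Counts of calls moved with most settings (6 higher and 14 lower as reported). Higher and lower calls numbered 0 and 0 with normexp, 3 and 0 with quantile normalization, with no filter and with the authors' values, and 0 and 0 over probes well above background on all 4 arrays, where 6 of the 20 called probes were tested. By limma, 2597 and 2410 probes had an unadjusted p under 0.05 with normexp and with that filter. They numbered 26 and 125 with eBayes trend and robust, 64 and 309 at an adjusted p under 0.1, 2 and 9 with specific probes, and 4 and 9 with the floor. Centring on the median gave 9 and 18, and the percentile over detected probes 8 and 13. Leaving out 1 array gave 0 to 8 higher and 0 to 12 lower; where a group then has 1 array, it is assumed to vary like the other. Shared replicate numbers do not establish pairing with 2 pairs: same-numbered arrays' deviations correlated at 0.116 across probes, and the replicate block gave 246 and 615 calls. Yet of the 116 probes that switched by at least 32-fold, 30 of 21 identifiers were bright on both arrays numbered 1 alone. Only 1 was bright on both arrays numbered 2 alone. The crossed pairs had 2 (control 1 with infested 2) and 0 (control 2 with infested 1). Whether same-numbered samples share an origin therefore stays open. The other 2 splits of the 4 arrays into equal groups gave 0 calls each by limma, with 494 and 248 probes at an unadjusted p under 0.05, against 20 calls and 2800, too few splits for a share under 0.05. In those splits any difference between infested and control arrays enters the residual spread and lowers the counts. The contrast therefore overstates how far the real split stands out.

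Of 26 lists 4 passed; 2 passed with no filter, 0 with specific probes, 0 with an estimated correlation, 0 with fry and 3 to 8 with 1 array left out. The fat body list passed in all 4 leave-one-out runs, with medians of -1.03 to -0.468. Centring on the median shifted the median of all probes to 0.127 and that of the epidermis and cuticle list with it, to 0.056, where the list passed in the lower direction (limma camera, adjusted p = 0.0482); this change of sign comes from the shift. Other lists that passed only in some settings were pattern recognition, serine protease inhibitors, oxidative stress defence, lysosome and V-ATPase, cytoplasmic ribosomal proteins and proteasome. Named genes kept their sign in 1862 of 1868 values, but the way they were chosen largely sets this count. Genes named per direction had to have both infested arrays on one side of both controls. For such genes, leaving out 1 array cannot turn the sign of the difference. Most members named for their small p lay the same way, so the count is not a measure of robustness. Causes were not tested, except that fewer probes were tested with the stricter filter and specific probes. With no filter the median of all probes was -0.106.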

Other observations

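The array carries probes named for flies and mosquitoes, which are relatives of the uzi fly. Of 516 such probes 31 were well above background in both arrays of a group, with a median log2 difference of -0.0701, 6 higher and 12 lower in both infested arrays. Only 2 were well above background in both infested and neither control array, and 3 the other way round. A single one passed, AGAP006910-RA, which was at least 2.83-fold lower in infested hemocytes (limma adjusted p = 0.0423), where it was not well above background.

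The heat shock list holds small heat shock proteins and large chaperones. Over 42 small heat shock identifiers the median log2 difference was -0.286, 20 were lower and 5 higher in both infested arrays, and the values ran from -3.81 to 0.88. Over 21 large heat shock proteins and chaperonins the median was -0.0158, with 2 lower and 0 higher in both infested arrays. Whether the families differ was not tested.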
